A study of Caenorhabditis elegans with 2 samples.

How the data were processed

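Whole worms of the strain fem-1 were lysed in TRIZOL and small RNA libraries were made with an Illumina small RNA protocol, per the labels' protocols. The series describes 2 libraries, labelled monophosphate and polyphosphatase, 1 per group. The processed data were 1 list of clusters of overlapping reads with no sample of its own. It was assigned to the monophosphate library because its name abbreviates that library's title and no other, and every one of its 51569 lines says that 1 library supports it. Values of the polyphosphatase library were not analysed here, and the comparison of the libraries was not made. The submitters' processing notes name Bowtie2 2.1.0. The genome build, the annotation release, adapter trimming and filters were not given in the sources used here.

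The deposited list gives read counts per cluster as raw counts of 1 library, without normalization, and the number of distinct sequences, edits to the genome, cluster width, a measure of how unique the placement was, and the annotation in sense and antisense. A separate column of the deposited list holds counts of conversion events, equal to the attribute of that name on all 51569 lines. A score column, which the deposited list repeats as the entropy of the cluster without a unit, was not used. Each line's width equals its end minus its start plus 1. The list holds 1417144 reads, 4791 of them on a sequence named markov that spans 99.9 Mb, against 100.2 Mb for the summed last positions of the chromosomes. This sequence was kept out of all shares on chromosomes. What it is was not given in the sources used here; it was taken as a background for randomly placed reads because of its span. The list's name states a length selection of 18 to 26 nt, so its total is not the library depth.

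Each cluster was put in 1 class from the deposited annotation, in the order rRNA, tRNA, snRNA, snoRNA, miRNA, piRNA, other non-coding RNA, transposon, protein-coding exon in sense, exon in antisense, intron, intergenic. Pseudogenes were counted with other non-coding RNA. Non-coding and transposon annotation was read on the cluster's own strand only, ahead of coding exons. The planned rule that annotation must cover 50% of a cluster could not be applied, since overlap lengths are not recorded. Cluster width stood in for read length, as read sequences are not listed. For the same reason first bases and 5′ end positions were not analysed, and the 21 nt clusters were compared with other widths instead of with 21 nt reads of other first bases. A cluster of the miRNA class that names 2 miRNAs counts for both, which applies to 3 clusters and 4 miRNAs, mir-789-1 and mir-789-2 sharing all their reads. Arms were compared where a miRNA had clusters of at most 30 nt for both arms within 150 nt. For the overhangs, the ends of narrow clusters on opposite strands were compared over -10 to 10 nt.

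Genes were named as the deposited list names them. Of 2429 gene identifiers, 2372 (97.7%) were in the table of gene names. The gene lists, fixed before the data were examined, were ERGO-1-type targets, sperm, oocyte and embryo, yolk protein, RNAi self-target, replication histone, collagen, muscle structure and ribosomal protein genes. They were looked up in the WBcel235 gene table, used for names and gene types only because its positions did not match: of 84 miRNAs, the leading cluster of 41 lay inside the hairpin given there. The 20259 genes compared were the 19983 protein-coding genes of that table and 276 others whose coding exons the deposited list names. All list members were found. Lists were compared with 10000 random lists of the same size (seed 7), matched on sense reads in bins of log2(reads + 1) for antisense values and unmatched for sense values. Matching on gene length, as planned, was left out because the builds differ. A random list could hold a gene more than once.

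Named genes followed a rule set before the data were examined. They were the 20 miRNAs with the most reads, the 10 protein-coding genes with the most antisense reads at 26 nt and the 10 at 22 nt, members of the fixed lists among the leading 50 of either ranking, and the 5 genes with the most reads in each non-coding class. Shares have exact (Clopper-Pearson) and counts exact Poisson 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals and the one-sided limit of 3 counts for a count of 0 cover counting error only. No test between conditions was made. The list comparison was tested on simulated data for all 20259 genes. Of 100 lists of 30 genes with 1 added antisense read per gene on average, 100 passed the 95th percentile, and of 100 unchanged lists 6 did. The simulated counts were Poisson with low means, and only the list mean was scored. These rates therefore do not carry over to the more skewed deposited counts, or to medians and shares of members. Of 300 duplexes planted among 20000 random clusters, 300 were found. They were exact 22 nt pairs with 2 nt overhangs at both ends, so their recovery checks the code only. It does not show how sensitive the count of single ends is in clusters merged from overlapping reads. Alternatives set before the data were examined were counting each cluster once, at least 10 reads per cluster, leaving out the 10 loci with the most reads, leaving out sequences that fit several positions (a uniqueness value under 20, a limit chosen after the data were seen), other length windows, all of chromosome IV, and duplexes without miRNA clusters. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.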

Results

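Small RNAs were sequenced from whole Caenorhabditis elegans of the strain fem-1, named for a sex-determination gene whose loss keeps the hermaphrodite germ line from making sperm. The series holds 2 libraries, 1 in each of 2 groups. The monophosphate library was made to catch small RNAs with a 5′ monophosphate, which miRNAs, piRNAs and primary siRNAs carry. The polyphosphatase library was made to catch also the triphosphate-bearing secondary siRNAs. Values of the monophosphate library are reported; the polyphosphatase library was not analysed here, so the libraries were not compared. With 1 library per group there was no replicate, no test between conditions and no p-value, and every interval below is an exact 95% interval that covers counting error only. The deposited values were 51569 clusters of overlapping reads with 1417144 reads. Of these, 49661 clusters with 1412353 reads lay on the nuclear chromosomes or the mitochondrial genome, and the others on a sequence named markov. Because the file holds reads of a selected length range, this total is the depth of the deposited clusters and not of the library, and shares refer to it. Positions are those of the deposited clusters; their genome build was not given in the sources used here.

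The first question was which transcripts the small RNAs came from. miRNAs took 764909 of the reads on chromosomes, or 54.2% (95% interval 54.1 to 54.2), in 237 clusters. Ribosomal RNA took 497248 reads, or 35.2% (35.1 to 35.3), and most of the remainder lay in protein-coding exons, piRNA loci and intergenic sequence. Reads in the sense direction of protein-coding exons numbered 68059 (4.82%, 4.78 to 4.85) in 34636 clusters, and reads antisense to such exons numbered 11097 (0.786%, 0.771 to 0.800) in 6050 clusters. Annotated piRNA loci held 35047 reads (2.48%, 2.46 to 2.51) in 1913 clusters, all on chromosome IV. Intergenic sequence held 19587 reads (1.39%, 1.37 to 1.41), introns 2455 reads in sense and 2502 in antisense, and transposons 2160 reads. Counting every cluster once, miRNAs made up 0.477% of clusters, since the median cluster held 1 read and 74.2% of clusters consisted of 1 read.

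Among structural RNAs, 447418 reads fell on a cluster at chromosome I 15064202 to 15068335 over rrn-2.1 and rrn-3.1, and 49830 on a cluster at I 15060285 to 15061139 that overlaps F31C3.10 and a large-subunit rRNA repeat. snoRNAs held 5032 reads, led by Y39G10AR.24 with 513 (95% interval 470 to 559; I 2410191 to 2410257), C51F7.3 with 333, Y75B12B.12 with 316, F01D5.12 with 256 and Y74C9A.6 with 211. tRNAs held 561 reads, of which 228 (199 to 260) lay on WBGene00014420 at V 14231342 to 14231411, 73 on WBGene00023207, 37 on WBGene00014416, 25 on WBGene00014448 and 24 on F35A5.5. snRNAs held 484 reads, with sup-39 at 129 (108 to 153; II 6968452 to 6968490, a cluster that is also annotated as mir-1831 and counted here as snRNA alone), F10D2.13 at 112, C27H5.11 at 39, F56H6.15 at 36 and sup-6 at 29. Other non-coding RNAs held 3212 reads. Their leading genes were K10H10.11 with 586 reads (540 to 635, at II 14496993 to 14497040), F08G2.13 with 218, and non-coding transcripts of rpl-3 with 193. Mitochondrial clusters of this class that name MTCE.3, MTCE.4 and MTCE.7 held 475 reads, and those that name MTCE.31 and MTCE.33 held 338. Which of these mitochondrial genes gave the reads, and whether it is protein-coding or rRNA, was not resolved.

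The length of a cluster separated these classes. Clusters of 18 to 26 nt, called narrow here, numbered 43609 on chromosomes and held 621514 of the 1412353 reads. Counted once each, narrow clusters were most frequent at 21 nt (18.1%, 17.7 to 18.4) and 22 nt (13.8%, 13.47 to 14.12). Annotated piRNA clusters were 21 nt wide in 81.5% of cases (79.6 to 83.2), and clusters antisense to exons peaked at 22 nt with 31.0% (29.8 to 32.2). Sense exon clusters had no such peak and fell from 13.4% at 18 nt to 9.33% at 26 nt. By reads the picture was set by miRNAs: 77.9% of the reads in narrow clusters (77.8 to 78.0) lay in clusters of 24 to 26 nt, of which 95.4% (95.4 to 95.5) were miRNA reads, and 19.1% (19.0 to 19.2) in clusters of 21 to 23 nt. Cluster width is the outer span of all overlapping reads and so an upper bound on read length. In the 39457 clusters with 1 distinct sequence it is the span of that sequence on the genome, which insertions or deletions can set apart from read length (4 of them were wider than 26 nt); there the 21 to 23 nt share was 47.8%.

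**Figure D1:**
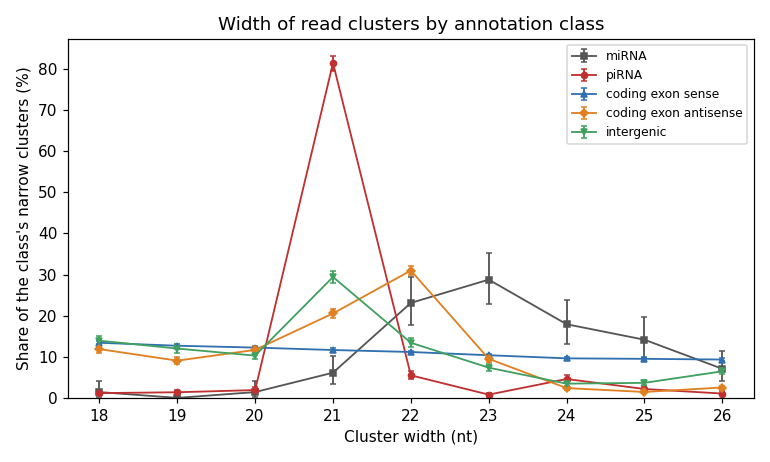
Share of each class's narrow clusters (y axis, percent) at each cluster width (x axis, nt) in the monophosphate library; points are shares of clusters counted once, and bars are exact 95% intervals for counting error. piRNA clusters peak at 21 nt (81.5%), exon-antisense clusters at 22 nt (31.0%), and sense exon clusters decline from 13.4% to 9.33%.

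miRNA levels, the products of Dicer cleavage of hairpins, were unequal. Reads were assigned to 154 miRNAs, of which 39 had at least 1000 reads and 39 had fewer than 10, and the 20 with the most reads took 89.2% of miRNA reads. mir-82, a member of the mir-58 or bantam-type family, had 153384 reads (95% Poisson interval 152617 to 154154), 20.1% of miRNA reads, at X 2435267 to 2435290 in an intron of T07D1.2. mir-228, linked to glia, followed with 104235 reads (103603 to 104870; IV 5562026 to 5562050, outside coding introns). mir-58 had 72522 reads (71995 to 73052; IV 3233265 to 3233333, in an intron of Y67D8A.1), mir-72 53865 (II 2452854 to 2452920), mir-80 51680 (III 8865190 to 8865256), mir-40 45106 (II 11538152 to 11538177), mir-57 37520 (II 7850487 to 7850513), mir-35 27144 (II 11537584 to 11537605), mir-90 16890 (III 8873907 to 8873931) and mir-237 16828 (X 8154041 to 8154065). The remaining 10 of these 20 ranged from mir-64 with 13515 reads to mir-238 with 7691, and were mir-64, mir-81, mir-65, mir-48, mir-39, mir-71, mir-37, mir-246, mir-235 and mir-238. Of the 20, 3 lay in a coding intron in sense (mir-82, mir-58 and mir-71, the last in ppfr-1) and 5 opposite to one (mir-40, mir-35, mir-81, mir-39 and mir-37).

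**Figure D2:**
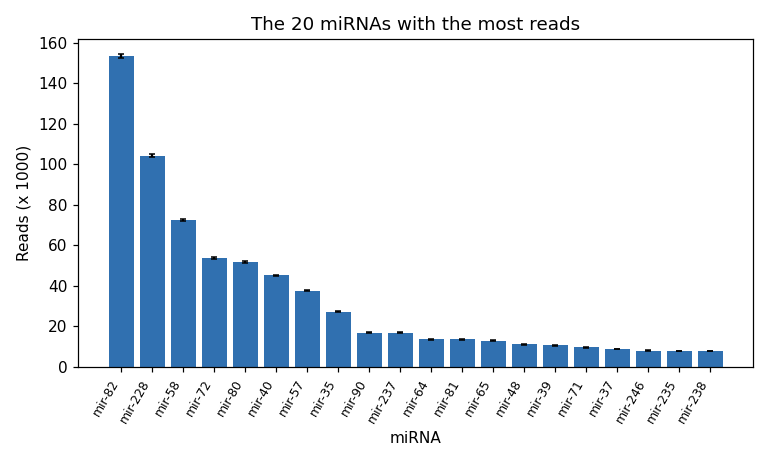
Reads (y axis, in units of 1000, linear from 0) of the 20 miRNAs with the most reads (x axis) in the monophosphate library; bars are counts and whiskers exact 95% Poisson intervals. mir-82 stands at 153384 reads and mir-238 at 7691.

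By family, the mir-58 family took 38.1% of miRNA reads (37.9 to 38.2), with mir-82 at 52.7% of the family, mir-58 at 24.9%, mir-80 at 17.8% and mir-81 at 4.63%. The mir-35 family, expressed in oocytes and embryos, took 12.5% (12.5 to 12.6) with reads for all 8 members; mir-40 (45106 reads) and mir-35 (27144) led it, and mir-41 had 31 reads. The mir-72 family took 7.81% (7.75 to 7.87), the mir-64 family 4.38% (4.33 to 4.43), the mir-51 family 2.40% (2.36 to 2.43), and the lin-4 family 2.37% (2.33 to 2.40), of which mir-237 was 93.0% and lin-4 itself 7.02%. The let-7 family, heterochronic regulators of late larval development, took 1.94% (1.90 to 1.97), with mir-48 at 11105 reads, mir-84 at 1797 and let-7 at 1401. The mir-44 family took 0.932%, the mir-2 family 0.225%, the mir-46 family 0.223%, the mir-75 family 0.120% and the mirtrons, which bypass Drosha, 0.0248% (190 reads). Near-identical family members share sequence, so reads can be exchanged between them. The uniqueness value of the leading cluster was 10 and 9 for mir-44 and mir-45, and 9 and 13 for mir-46 and mir-47. It was 22 and 16 for mir-64 and mir-65, against 43 each for mir-81 and mir-82. The share of the mir-58 family rests on few loci. Without the 10 loci with the most reads, which include mir-82, mir-58 and mir-80, it fell to 6.14%. That fall follows from removing these members, and the shares of other families were not recomputed.

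miRNAs linked to a tissue were also unequal. Glial mir-228 took 13.6% of miRNA reads (13.6 to 13.7) and the oocyte and embryo group 12.5%. The seam and epidermis group (mir-48, mir-84, mir-241) took 1.71% (1.68 to 1.74), the intestinal mir-60 0.184% (1407 reads), the somatic gonad pair mir-240 and mir-786 0.171% (1311 reads), muscle mir-1 0.0651% (498 reads) and the neuronal group of mir-124, lsy-6 and mir-791 0.0119% (91 reads). These are shares of reads, and ligation and amplification differ between miRNA sequences.

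Hairpin arms were used unevenly. In 45 miRNAs that had at least 100 reads in separate clusters for both arms, the median share on the major arm was 99.6%, and it exceeded 95% in 36 of them. The major arm was the 5′ arm in 20 and the 3′ arm in 25. let-7 (99.8%), lin-4 (99.9%) and mir-228 (99.98%) used the 5′ arm and mir-82 (99.999%) and mir-35 (99.9%) the 3′ arm. The share was under 80% in 4 miRNAs, named after their values were seen: mir-63 with 72.1% (67.5 to 76.4), mir-229 with 65.2% (62.1 to 68.2), mir-34 with 58.5% (54.6 to 62.4), and mir-243 with 142 reads against 141 (50.2%, 44.2 to 56.2). Read starts are not given per read, so precision of the 5′ end was not analysed here. With arms weighed by distinct sequences the median was 91.5%.

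The next question was how far 21 nt RNAs came from the piRNA regions of chromosome IV. piRNAs, called 21U-RNAs in worms, carry a monophosphate and do not need Dicer. Of the reads in 21 nt clusters, 78.2% (77.8 to 78.7) lay in 2 windows of chromosome IV that were fixed before the data were examined. In the first window annotated piRNA clusters ran from 4834598 to 6494709 (173 clusters, 1517 reads), and in the second from 13604179 to 17191286 (1724 clusters, 33424 reads). Leaving out miRNA and rRNA clusters, the windows held 33.3% of 21 nt clusters (32.3 to 34.4) and 5.79% of clusters of the other narrow widths (5.55 to 6.04); by reads the shares were 79.1% and 31.7%. Annotated piRNA clusters lay in the windows in 99.2% of cases. The piRNAs with the most reads were 21ur-3926 with 1920 (1835 to 2008; IV 14287357 to 14287377), 21ur-1684 with 1255 (IV 16577693 to 16577713), 21ur-705 with 1110 (IV 15238749 to 15238772), 21ur-38 with 861 (IV 16788989 to 16789009) and 21ur-3215 with 731 (IV 15536992 to 15537012). Counted once each, 33.3% of all 21 nt clusters lay in the windows, against 78.2% by reads. The first base is not given per read, so 21U identity rests on width, position and annotation.

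**Figure D3:**
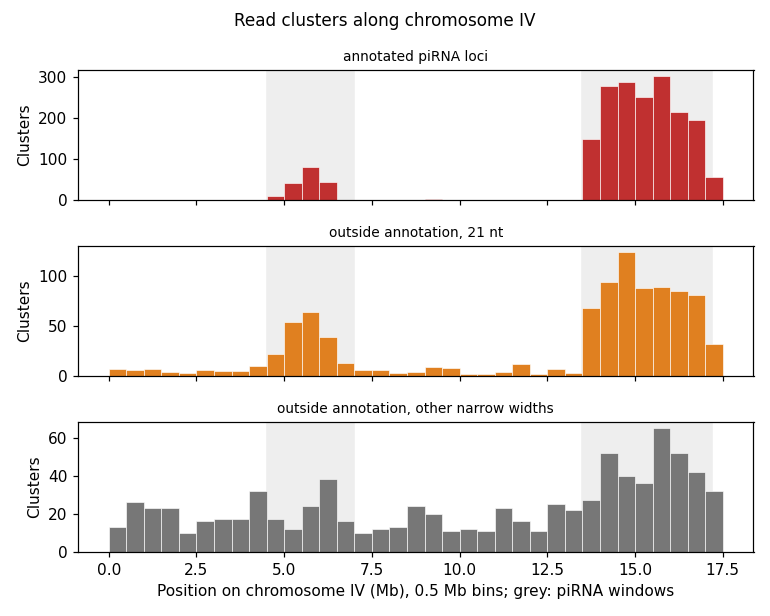
Number of clusters (y axes) in 0.5 Mb bins along chromosome IV (x axis, Mb) in the monophosphate library, for annotated piRNA loci, for intergenic or intronic clusters of 21 nt, and for such clusters of the other narrow widths; grey marks the 2 windows. Of the intergenic or intronic 21 nt clusters of all chromosomes, 841 of 1571 lie in the windows.

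Small RNAs antisense to messenger RNAs were examined for the lengths of primary (26G) and secondary (22G) siRNAs. Among reads classed as exon sense or exon antisense, 35.0% were antisense in clusters of 22 nt (33.8 to 36.2, 2058 reads). At 21 nt 27.4% were antisense (26.2 to 28.6). The share was 5.18% at 24 nt (4.48 to 5.94) and 4.31% at 25 nt (3.68 to 5.01), and rose again to 16.3% at 26 nt (15.2 to 17.5; 701 reads in 144 clusters). From 18 to 20 nt it lay between 15.47% and 17.16%. The 26 nt reads were concentrated: 90 genes had any, and the leading 10 held 69.6% of them. The 22 nt reads were spread over 1367 genes, 1005 of which had 1 such read, and the leading 10 held 5.52%. The 26 nt share depends on these few loci: counting each cluster once it was 4.93% (4.18 to 5.78), still above 24 nt (4.54%) and 25 nt (2.82%) but within the counting interval of 24 nt. The first base was not available, so 26G and 22G siRNAs could not be separated from other RNAs of the same length. Reads of 22 nt merged into wider clusters are not in the 22 nt counts. Their spread over genes is thus that of 22 nt clusters alone. Sense reads with a non-coding or transposon annotation were in other classes, while antisense reads to the same exons stayed, which can raise the antisense shares. At 22 nt other non-coding RNA and transposons held 47 and 196 reads, against 3821 sense exon reads.

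**Figure D4:**
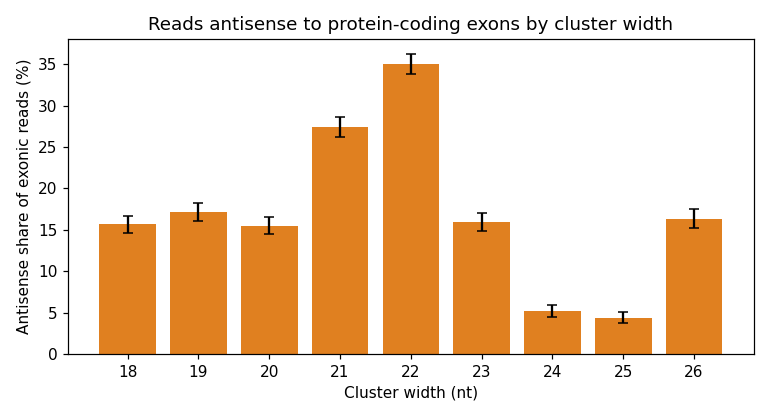
Percent antisense (y axis) among reads classed as exon sense or exon antisense, by cluster width (x axis, nt) in the monophosphate library. Whiskers are exact 95% intervals for counting error. The share is highest at 22 nt (35.0%), falls to 4.31% at 25 nt and is 16.3% at 26 nt.

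By gene, 5 of the 10 with the most antisense 26 nt reads were on the list of targets of ERGO-1, an Argonaute that binds 26G siRNAs in oocytes and embryos. They were E01G4.7 with 185 reads (95% Poisson interval 159 to 214; leading cluster II 13478283 to 13478308, exon 2), C40A11.10 with 72 (56.3 to 90.7; II 2136563 to 2136588, exon 3), F52D2.6 with 35 (24.4 to 48.7; X 1976243 to 1976268), E01G4.5 with 29 (II 13473648 to 13473673) and Y43F8B.9 with 13 (6.92 to 22.2; V 19479855 to 19479880). Outside the list were C28C12.2 with 100 reads (81.4 to 122; IV 8500002 to 8500027, exon 2), F59C12.4 with 15 (X 16602417 to 16602442), and T02G6.4 (I 11809725 to 11809750), Y82E9BR.20 (III 1374729 to 1374754) and Y82E9BR.6 (III 1381597 to 1381622) with 13 each. A further 9 list members were among the leading 50, namely Y37E11B.2 with 7 reads, F39E9.7 and F55C9.3 with 6, H16D19.4 and Y17D7B.4 with 5, K02E2.6 with 3, and T08B6.2, W04B5.1 and W04B5.2 with 2. In the WBcel235 gene table E01G4.7, F39E9.7, H16D19.4, T08B6.2, W04B5.1 and W04B5.2 are pseudogenes and C40A11.10 a miRNA gene, whereas the deposited annotation treats them as coding.

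The ERGO-1 list as a whole stood apart from other genes. Its 28 members held 372 of the 701 antisense 26 nt reads, or 53.1% (49.3 to 56.8), and 14 of the 28 had such reads. Among 10000 random lists of 28 genes matched on sense reads the median was 0% of members and the highest 14.3%. For antisense reads of any width, 22 of 28 members had reads (1186 in total), with a median of 30 reads per member, above that of every random list. In sense, 21 of the 28 had reads (522 in total, a median of 5 per member), at percentile 99.99 of random lists of that size for the number of members. Besides the genes above, fbxb-37 had 94 antisense reads, T05E12.8 88, C44B11.6 42, F55C9.5 30 and ZK380.5 30, mostly in clusters wider than 26 nt. No antisense read was found for C08F11.7, ZK402.5, F14F7.5, fbxa-65, K06B9.6 and E01G4.3. In clusters of 22 nt the list did not stand apart, with 10 reads in 6 members, at percentile 79.4 of the random lists. Read lengths inside wider clusters are not known, so 22 nt reads merged there are not counted. The level of 22 nt reads on the list is therefore not settled. Among genes now listed as protein-coding, 19 members were left, of which 7 had antisense 26 nt reads (36.8%, against at most 21.1% in random lists); they held 98 of 389 such reads, or 25.2% (20.95 to 29.81).

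At 22 nt the genes with the most antisense reads were K09H11.11 with 24 (15.4 to 35.7; V 5754928 to 5754949, exon 2), F39E9.10, now listed as a long non-coding RNA, with 18 (10.7 to 28.4; II 3303242 to 3303263), the F-box gene fbxb-97 (II 1847601 to 1847622) and the immunophilin gene fkb-8 (I 12917223 to 12917244) with 12 each, Y71A12B.17 with 10 (I 13987723 to 13987744), T12G3.1 (IV 12034377 to 12034398), bath-45 (II 13123264 to 13123285) and klp-20 (III 227421 to 227442) with 8 each, and C04G2.10 (IV 10117942 to 10117963) and R02D3.7 (IV 254416 to 254437) with 7 each. For klp-20 and R02D3.7 the leading cluster held as many edits as reads. Of the fixed lists, the collagen col-71 with 6 reads (II 3500533 to 3500554) and E01G4.5 with 5 (II 13472676 to 13472697) were among the leading 50.

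The other lists had at most 56 antisense reads each. Sperm genes, the targets of the other 26G pathway, had 16 sense reads in 7 of 92 members, fewer members than in any random list of that size, and 7 antisense reads, none at 26 nt. The lowest uniqueness value of any cluster was 1, so reads that fit several positions equally well may be missing. Counts for families of similar genes, such as the msp- genes of the sperm list and the his- genes, may then be too low. A count of 0 there does not show absence of RNA. Oocyte and embryo genes had 1877 sense reads with all 30 members represented, and 54 antisense reads in 20 members, none at 26 nt and 10 at 22 nt. Yolk protein genes had 10066 sense reads, 14.8% of all sense exon reads (14.5 to 15.1), led by vit-6 with 4468, vit-2 with 2451 and vit-5 with 1721, and 1 antisense read. Muscle structure genes had 520 sense reads in 14 of 15 members and 2 antisense reads. Ribosomal protein genes had 4285 sense reads in 71 of 78 members and 56 antisense reads, of which 2 were at 26 nt. Among the members counted without sense reads was rpl-3, on which 193 reads were classed as other non-coding RNA. The sense values of the ribosomal protein list are thus lower limits. Replication histones, taken as every gene with a his- symbol whatever its histone type, had 274 sense and 25 antisense reads over 72 genes. Of these antisense reads 21 lay on his-24. Collagens had 676 and 29 over 156 genes, and the RNAi self-targets eri-6, eri-7 and sosi-1 together 4 and 5. For these 3 self-targets the mean number of antisense reads lay at percentile 95.5 of the random lists, and at 98.0 for 22 nt, where it rests on 3 reads in 1 gene. Of the antisense reads of these last 3 lists, none was at 26 nt. For a list with 0 reads at 26 nt, a count of 0 allows up to 3 reads as a one-sided limit.

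Dicer cuts double-stranded RNA into duplexes with 2 nt 3′ overhangs, and pairs of narrow clusters on opposite strands were searched for that geometry. There were 757 overlapping pairs. A 2 nt overhang was seen at 49 ends (95% Poisson interval 36.3 to 64.8), against a median of 42.0 and a range of 30 to 64 for the 20 other overhangs from -10 to 10 nt, of which 5 were as frequent. Both ends had the 2 nt overhang in 3 pairs. In protein-coding exons the counts were 32 ends against a median of 30 (609 pairs), and in piRNA loci, introns and intergenic sequence 14 (7.65 to 23.5) against a median of 6.50 and a highest count of 21 (129 pairs), where 3 other overhangs were as frequent. In this last set the 2 nt count lay above the median of the others beyond its counting interval, without being the most frequent overhang; over all pairs and in exons an excess at 2 nt was not detectable at this depth. Both arms of a miRNA hairpin lie on the same strand and were not counted.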

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

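The tests in this part were all chosen after the result was seen. Reads on the sequence named markov, which belongs to no chromosome, numbered 4791 (0.338% of all reads) in 1908 clusters, flagged because they lie outside the comparisons and number more than 3, a bar that does not show them to be unexpected. What the sequence is was not given in the sources used here, and comparisons with it assume that it shows where reads land at random. Reads on it carried 0.956 edits per read, against 0.0124 for miRNA reads. In 1749 of the 1908 clusters the edits numbered at least as many as the reads, called all-edited here. Since a read can hold several edits, an all-edited cluster can include reads without one. All-edited clusters also lay on chromosomes, 2036 of them with 3886 reads. Among them were clusters antisense to lin-35 (138 reads, I 5815259 to 5815277), ent-3 (96 reads, V 14235033 to 14235053) and Y59A8A.2 (60 reads, V 17876859 to 17876877).

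From 18 to 20 nt, chromosomes held 1590 such clusters and the markov sequence, of near-equal span, 1632, a ratio of 0.974 (95% interval 0.909 to 1.04). Under that assumption random placement of short reads may account for all-edited clusters of these widths. At 21 nt the counts were 162 and 89, a ratio of 1.82, and from 22 to 26 nt they were 275 and 28, a ratio of 9.82 (6.65 to 15.1), which argues against random placement as the whole cause of the number of clusters there. By reads the 22 to 26 nt counts were closer, 504 and 298, of which 77 and 264 lay at 23 nt. All-edited clusters held 7.66% of exon-antisense reads, and no biological explanation was tested.

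Conversion events, a column not used in the comparisons, numbered 2084 in 519 clusters and were flagged by the same bar. They were most frequent per read on the markov sequence (0.0632) and in sense introns (0.0538), and were 0.000507 per miRNA read.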

How the results depend on the processing

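Alternatives that leave out all-edited clusters, keep clusters of 1 distinct sequence or keep genes now listed as protein-coding were chosen after the data were seen. Of 47 alternative values for 10 results, 5 equalled the reported value, 12 others lay within its interval (counts: within 1.5 times) and 30 did not; unless stated, the cause was not tested. Counting each cluster once gave 41.4% of narrow clusters at 21 to 23 nt, 0.477% miRNA, 0.844% mir-82, 2.11% mir-58 family, 33.3% of 21 nt clusters in the windows and 4.93% antisense at 26 nt; this follows from loci with many reads. With at least 10 reads per cluster the values were 16.8% at 21 to 23 nt, 57.0% miRNA, 94.2% in the windows, 100% antisense at 26 nt, 3 ERGO-1-type members, 1 end with a 2 nt overhang and a median of 96.8% on the major arm; fewer clusters remain by construction. Without the 10 loci with the most reads they were 31.5% at 21 to 23 nt, 59.4% miRNA and 6.14% mir-58 family. Without sequences that fit several positions they were 19.2%, 56.1% and 38.8%. Without all-edited clusters miRNAs took 54.3% and the windows 79.3%. Clusters of 1 distinct sequence gave 47.8% at 21 to 23 nt, 59.1% in the windows, 5.17% antisense at 26 nt and 36.4% at 22 nt. All of chromosome IV held 81.8% of 21 nt reads; antisense shares were 10.8% at 25 to 26 nt and 27.1% at 21 to 23 nt. Genes now listed as protein-coding left 7 ERGO-1-type members. Arms weighed by distinct sequences gave 91.5%. Leaving out the 10 loci removed no 21 nt or narrow exon cluster and says nothing of those shares. Of the 5 settings that changed them, the antisense share at 26 nt exceeded that at 24 and 25 nt in 5, and 22 nt was highest in 4, all but that of at least 10 reads. Not run were the overlap rules and first-base shares, since the values they need are not listed per cluster. No paired analysis was possible because values of 1 library were analysed and no result came from a test between groups.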

Other observations

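Comparisons with the markov sequence assume that it shows where reads land at random. Apart from the test of distance to annotated piRNA loci, the tests and loci in this part were chosen after the result was seen. Sense exon reads were led by the yolk gene vit-6 (4468 reads), vit-2 (2451) and vit-5 (1721), then F43E2.6 (1403), the elongation factor gene eft-3 (716), vit-1 (679), vit-4 (394), vit-3 (353), H02I12.1 (349), the elongation factor gene eft-2 (340) and the heat shock protein gene daf-21 (325). Lower down, the eggshell genes cpg-1 and cpg-2 had 252 and 205. F43E2.6 was the exception among these in its antisense reads, 1085 against at most 6 for the others named here. Both strands were covered at II 7367528 to 7367560 (1085 reads, 34 distinct sequences) and II 7367526 to 7367570 (1403 reads, 93 distinct sequences) in a coding exon. The antisense cluster had 0.179 edits per read, against 0.101 over all exon-antisense clusters, and the sense cluster 0.267, against 0.0312 over all sense exon clusters. Neither had a conversion event.

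Overlapping clusters of at least 10 reads on both strands made up 38 pairs, 16 of them with a coding exon. Of the 12 genes in those 16 pairs, 6 were on the ERGO-1 list: W04B5.2, Y37E11B.2, T05E12.8, F55C9.3, F55C9.5 and K02E2.6. The others were F39E9.10, F43E2.6, C39B5.2, Y105C5A.14, Y116A8B.1 and Y116F11A.1. At T05E12.8 the sense cluster at V 17069322 to 17069346 held 98 reads and the antisense cluster at 17069320 to 17069347 held 10. Among intergenic clusters the most reads lay at IV 15388235 to 15388256 (1771 reads), II 2681443 to 2681475 (1008), IV 8428586 to 8428621 (524) and IV 13747780 to 13747800 (500). Among the 20 leading miRNAs, mir-72 had the most edits per read (0.0270) and mir-37 the fewest (0.00410).

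Clusters of 21 nt outside annotated RNAs and exons were concentrated in the piRNA windows of chromosome IV. Of 1571 such clusters 53.5% (51.0 to 56.0) lay in the windows, against 11.4% (10.4 to 12.5) of the other narrow widths, which measures the pattern and tests no explanation of it. By reads the shares were 75.4% against 45.5%, with 77.8% at 22 nt and 77.2% at 24 nt, but without the 5 clusters with the most reads of each width they were 70.5% (69.1 to 71.9) at 21 nt, 34.2% at 22 nt, 28.5% at 24 nt and 16.8% (15.9 to 17.8) over the widths other than 21 nt. Random placement as the source of the number of these 21 nt clusters is argued against by a ratio of 14.96 (12.3 to 18.4) to markov clusters of 21 nt. That ratio counts clusters of all chromosomes and does not address their concentration in the windows. Spill-over from annotated loci is argued against by distance, as 5.11% (3.72 to 6.83) of the 841 in the windows lay within 50 nt of an annotated piRNA cluster. This covers only clusters beside such loci, since clusters that overlap an annotated piRNA on its strand were classed as piRNA. That the 841 are piRNAs absent from the annotation used is a candidate explanation that stays open, untested without first bases.

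The 22 nt peak of exon-antisense clusters appeared in a library made to catch monophosphate ends. Random placement as the source of the number of antisense clusters at 22 nt is argued against by a ratio of 73.5 (49.2 to 115) to markov clusters. That ratio does not address the peak, since markov clusters fell with width, from 105 at 21 nt to 24 at 22 nt and 1 at 24 nt. Sense clusters, which had no peak, numbered 3321 at 22 nt. The antisense count at 22 nt was 4.40 times (4.05 to 4.79) the mean of 20 and 24 nt, against 1.02 for sense clusters. This measures the peak and tests no explanation of it. Dicer-type duplexes stay open: 4 ends of 22 nt antisense clusters had a 2 nt overhang, against a median of 3 for other overhangs over 59 pairs, too few to decide, and a passenger strand could be lost before sequencing. Secondary siRNAs carried over into this library also stay open, untested without first bases and the polyphosphatase values.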
